A study of Mus musculus with 2 samples.

How the data were processed

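RNA was measured in 2 libraries of mouse (BALB/c) dermal cells, 1 of cultured fibroblasts and 1 of cultured skin-derived precursors (SKPs). Per the labels' protocols, RNA was taken with Trizol, treated with DNase I, enriched for mRNA with oligo(dT) beads and made into Illumina libraries. Each library was placed in its group by the cell type in its labels. The cell types also differed in medium, in growth factors and in the age of the mice (postnatal day 3 for fibroblasts and 4 for SKPs), so a difference between the libraries cannot be assigned to cell type alone.

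Reads were 49 bases long, and 81.65% of 23374716 fibroblast reads and 85.13% of 22981183 SKP reads were mapped to genes with at most 2 mismatches, per the file headers and class names of the deposited mapping tables. The deposited percent values there are shares of total reads, and 61.95% and 63.44% of reads had a single match while 19.69% and 21.69% matched several positions. The deposited count of reads per gene is a whole number with no normalization, per the file headers, and summed to 18406244 reads for fibroblasts and 18949264 for SKPs. Although the header calls these reads unique, the totals exceed the reads with a single match by 3924587 and 4370357, and how reads at several positions or in overlapping genes were counted was not tested, so the split between paralogs is uncertain. The deposited RPKM values equal the reads of a gene scaled by its length and by those totals. The deposited coverage, in percent, is the share of the gene length under reads. The authors' comparison table gives log2 of the fibroblast over the SKP RPKM, with 0.01 in place of an RPKM of 0, and a p-value and FDR per gene from a test whose name is not given in the sources used here. The genome build was mm9, per the submitters' processing notes, and the aligner, the counting tool, the gene annotation and the strandedness are not given in the sources used here. Overlapping and antisense genes could therefore not be separated. The reference genome used here for names is of another build, so no coordinates are printed. Of the 17431 genes with a read, 17382 gene IDs were found in the reference table of gene names, 25 symbols that a spreadsheet had turned into dates were replaced by the gene ID, and 13 genes, 0 of them expressed, had different lengths in the per-library tables.

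From the deposited values the log2 ratio of SKP over fibroblast RPKM was computed per gene in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The 95% exact (Clopper-Pearson) counting interval of each ratio came from the read counts. PCR duplicates are not independent molecules, so intervals and floors cover counting error only. At these depths 1 read in a gene of 1 kb is worth 0.0543 RPKM in the fibroblast library and 0.0528 in the SKP library. A gene was called expressed at RPKM 1 or more and 20 reads or more in either library. An expressed gene counted as higher or lower when it was at least 2-fold apart and the interval excluded equality. A gene with 0 reads in a library was compared with a floor of 3 reads, and its ratio is a bound against that floor only. The exact interval limit, which also carries the counting error of the other library, is lower. No fold is given where a library had 0 reads and the other had no more than the floor of 3 reads. With 1 library per group no test of the cell types was possible, so no p-value was computed and neither a count model nor leave-one-out was run.

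The comparisons, gene lists, filters, alternatives and the rule for named genes were fixed before the data were examined. That rule names the 15 genes with the highest and the 15 with the lowest ratio, ranked by the interval limit nearest to equality, among genes with RPKM of at least 10 and at least 100 reads in the higher library. It adds the 5 genes with the highest RPKM of each library, every member of the SKP and neural crest list and of the sex-linked list, and from every other list up to 4 expressed members with the largest ratio and up to 2 with the highest RPKM. Genes outside the rule are named only where they make up a count of 5 or fewer, or in the closing observations, and were chosen after their values were seen. A few genes that the rule names are not reported here.

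The 36 lists hold 773 symbols, of which 32 had no read in either library and 1 was matched through its gene ID. They cover SKP and neural crest, dermal papilla and dermal fibroblast markers, collagens, contractile genes, serum response and YAP targets, pluripotency genes, markers of Schwann cells, neurons, melanocytes, keratinocytes, endothelium, leukocytes, mast cells, adipocytes, skeletal muscle, pericytes and bone, cell cycle genes, p53 targets and cell cycle inhibitors, FGF and EGF feedback, cholesterol synthesis, the Wnt, Notch, hedgehog and BMP pathways, Hox genes, matrix proteases, cytokines, interferon-stimulated genes, hypoxia and glycolysis, ATF4 and unfolded protein genes, imprinted genes, integrins, housekeeping genes and sex-linked genes. A few members stand in several lists, at most 5 shared by any pair. For each list with at least 3 expressed members, the median log2 ratio, with members at 0 reads taken at their bound, was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list was said to stand apart below percentile 2.5 or above 97.5. This describes these libraries and is no test of the cell types.

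The procedure was tested on simulated counts drawn around the pooled means of both libraries at their real depths, with 11736 genes passing the filter. Their noise was counting (Poisson) noise only, the model that the interval assumes, with no variation between cultures or from duplicates. Of 50 genes set 2.5-fold apart 98% were called, and of 50 each at 4-fold, 8-fold and 16-fold 100% were called. Of 11536 unchanged genes 6 were called, the interval held the true ratio in 95.39% of genes, and 9 of 200 random lists (4.5%) and 50 of 50 lists with planted differences were called. The planted lists held 8 raised genes among 12, so each median fell on raised genes and the 50 of 50 was all but fixed in advance. Genes were drawn independently, and far fewer were set apart than the 2227 called in the data. These results check the calculation under counting noise alone and do not bear on variation between cultures or on lists of co-regulated genes.

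Alternatives were scaling by TMM factors (edgeR 4.0.16 in R 4.3.3), by median-of-ratios size factors and to totals without the 50 most abundant genes, no expression filter, an RPKM filter of 5, log2(RPKM + 1), a 4-fold limit, an interval that excludes 2-fold, and unmatched random lists. Lists matched on gene length were added after seeing the data. These scalings shifted the log2 ratios by -0.02, 0.01 and -0.03. edgeR was used for the TMM factors only.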

Results

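Poly(A) RNA of 2 cultures from BALB/c mouse dermis was sequenced, 1 library per cell type. The fibroblast culture, from mice at postnatal day 3, was grown in DMEM with 10% fetal bovine serum. The culture of skin-derived precursors (SKPs), from mice at postnatal day 4, was grown with FGF2 at 40 ng/ml, EGF at 20 ng/ml and 2% B27 supplement. SKPs are multipotent dermal cells that are selected by their growth in these factors. The fibroblast library held 23374716 reads and the SKP library 22981183 reads, of which 81.65% and 85.13% were mapped to genes. Reads were found for 16282 genes in the fibroblast library and for 16727 genes in the SKP library. There were no replicates, so every difference below is a difference between these 2 libraries and has no replicate check. Members named because a count held 5 or fewer were chosen after their values were seen. The intervals in parentheses are 95% exact counting intervals, which cover counting error only.

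The labels set the transcriptome of SKPs against that of dermal fibroblasts. The SKP library held far more RNA of the extracellular matrix genes Col15a1 and Lum, of the matrix proteases Mmp9 and Mmp3, and of the imprinted growth genes H19, Igf2 and Dlk1, and 14 of 20 feedback and receptor genes of FGF and EGF signalling were at least 2-fold higher there. The fibroblast library held far more RNA of the smooth muscle and myofibroblast genes Acta2, Tagln and Cnn1 and of the R-spondin receptor gene Lgr5, and 19 of 24 cholesterol synthesis genes were at least 2-fold higher there. Markers of mast cells, adipocytes, keratinocytes and leukocytes were also higher in the SKP library. SKP and neural crest markers divided, with 5 of 17 higher there, among them Nes, and 4 lower, among them Sox10.

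Among 12053 expressed genes, 1455 (12.1%) were at least 2-fold higher in the SKP library and 772 (6.41%) were at least 2-fold higher in the fibroblast library. The other 9825 genes (81.5%) were under 2-fold apart, and 1 gene was at least 2-fold apart with an interval that included equality. At 16-fold the counts were 251 genes higher in the SKP library and 52 higher in the fibroblast library. Spearman's rho between the RPKM values of the libraries was 0.891 across expressed genes, which are not independent replicates. The 10 genes with the most reads took 9.43% (9.41 to 9.44) of the counted reads in the fibroblast library and 6.98% (6.97 to 6.99) in the SKP library. The most abundant transcripts of the SKP library were Crabp1, a retinoic acid binding protein of the dermal papilla (4616 RPKM against 1361 in fibroblasts), Eef1a1 (4176 against 5266), Spp1, which encodes osteopontin (3709 against 824), Lgals1 (3584 against 3457) and the imprinted non-coding RNA H19 (2599.6 against 105). In the fibroblast library Eef1a1, Col1a1 (4474 RPKM against 2161 in SKPs), Lgals1, the proteoglycan gene Bgn (3373 against 2545) and Actb (3363 against 1915) were the most abundant.

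**Figure D1:**
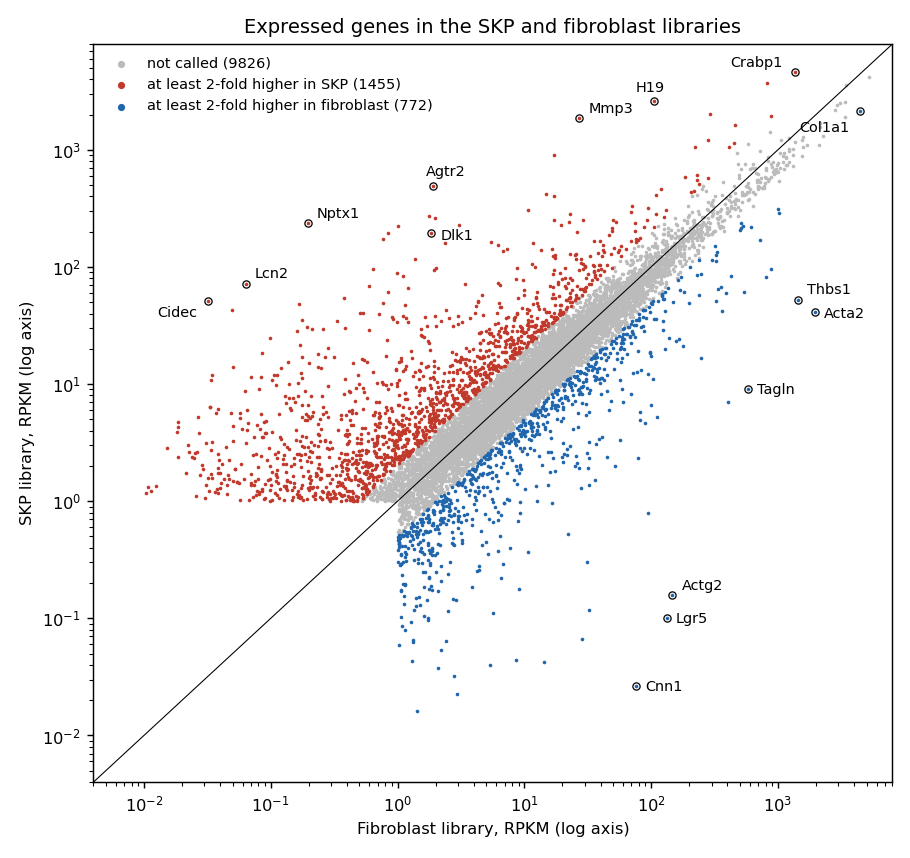
RPKM of each of the 12053 expressed genes in the fibroblast library (x axis, log scale) and the SKP library (y axis, log scale), with a gene at 0 reads drawn at the level of 3 reads. Red points are the 1455 genes at least 2-fold higher in the SKP library, blue points the 772 higher in the fibroblast library, and the line marks equal RPKM.

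Among the largest ratios in favour of the SKP library, Nptx1 (gene ID 18164), a secreted neuronal pentraxin, stood at 236 RPKM against 0.195, a 1205-fold difference (772 to 2002). Agtr2 (11609), the angiotensin type 2 receptor, stood at 495 RPKM against 1.89 and was 262-fold higher (215 to 322), and Ace (11421), which makes angiotensin II, was 233-fold higher (186 to 296). Cd34 (12490), a surface protein of progenitor cells and of a subset of dermal fibroblasts, was 227-fold higher (164 to 322). The basement membrane collagen gene Col15a1 was 223-fold higher, the keratan sulfate proteoglycan gene Kera 286-fold, and Sparcl1, a matricellular protein gene, 154-fold. Signalling and transport genes of the same group were Prkcb, a protein kinase C (214-fold), the muscarinic receptor gene Chrm3 (347-fold, with 2 fibroblast reads), the urea transporter gene Slc14a1 (253-fold) and the metalloreductase gene Steap4 (150.3-fold). Cidec, a lipid droplet protein of fat cells, Lcn2, an iron-binding defence protein, and Tpsb2, a mast cell tryptase, each had 1 read in the fibroblast library against 1647, 1160 and 891 in the SKP library. Tpsb2 is a close relative of Tpsab1, and reads may have been shared between them.

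On the fibroblast side, the R-spondin receptor gene Lgr5 (14160), a marker of hair follicle stem cells, stood at 133 RPKM against 0.101 in the SKP library, a 1319-fold difference (695 to 2886). Wnt4 was 103-fold higher in the fibroblast library (68.0 to 165), and Wisp2, a secreted CCN-family protein, was 273-fold higher (106 to 1003). Cnn1, which encodes calponin of smooth muscle, had 2785 fibroblast reads and 1 SKP read. Actg2, the enteric smooth muscle actin, was 936-fold higher (365 to 3436) and the actin nucleator gene Lmod1 423-fold (181 to 1303). The list went on with the sialic acid receptor gene Siglecg (337-fold, with 2 SKP reads), the pattern recognition molecule Ptx3 (119-fold), the adipokine-like C1qtnf3 (33.8-fold), the serine protease gene Prss23 (25.9-fold) and D4Bwg0951e (41.6-fold). Thbs1, an adhesive matrix protein that activates TGF-beta, was 27.7-fold higher (26.9 to 28.4) at 1449.8 RPKM against 52.4.

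Contractile genes formed the group with the lowest median. Of 20 expressed contractile and myofibroblast genes, 16 were at least 2-fold lower in the SKP library, 1 was higher and 3 were neither. Acta2, the smooth muscle actin that marks myofibroblasts, stood at 41.0 RPKM against 1953 and was 47.7-fold higher in fibroblasts (45.2 to 50.3). Tagln (64.0-fold), the myosin light chain gene Myl9 (56.7-fold), the smooth muscle myosin gene Myh11 (134-fold) and the tropomyosin gene Tpm1 (2.83-fold) were also higher there. The 1 member higher in the SKP library was Des, the intermediate filament of muscle, at 31.0 RPKM against 12.04. The list median was -1.53 on the log2 scale, below all 10000 random lists matched on expression, a description of these libraries. Acta2 and Actg2 share long stretches with other actin genes, so their split is uncertain.

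Serum response and YAP target genes divided. Of 22 expressed members, 10 were lower in the SKP library, 7 were higher and 5 were neither, with a median of -0.62 below all random lists. Lower in the SKP library were Thbs1, the matricellular YAP target Ctgf (21.0-fold, 18.4 to 24.0) and the vasoconstrictor gene Edn1, with 1 SKP read against 126. The growth factor response gene Egr2 went the other way, at 35.9 RPKM against 0.914 (39.2-fold, 29.6 to 53.1). With only genes at RPKM 5 or more, the list's median was -0.26 at percentile 7 and it no longer stood apart.

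Matrix genes differed in both directions. Of 26 expressed collagens, 12 were at least 2-fold higher in the SKP library, 5 were lower and 9 were neither, and the median of 0.98 lay above all random lists. Besides Col15a1, the fibril-associated collagen gene Col14a1 was 49.4-fold higher (43.4 to 56.4), Emid2 114-fold (52.0 to 311) and the transmembrane collagen gene Col13a1 253-fold, with 1 fibroblast read. The 5 collagens lower in the SKP library were Col1a1 (2.07-fold, 2.06 to 2.08), Col5a2, Col8a1, Col12a1 and Col4a5, while Col1a2 differed by 1.27-fold. Dermal fibroblast markers had 7 of 24 expressed members higher in the SKP library, 4 lower and 13 neither, with a median of 0.15 at percentile 99.2. Higher were Cd34, Dlk1, the small proteoglycan gene Lum (895 RPKM against 17.1, 52.4-fold) and Fap (11.7-fold), a serine protease of activated fibroblasts. The 4 lower members were Col1a1, Thy1, S100a4 and Ly6a, of which Ly6a may share reads with its relatives, and the intermediate filament gene Vim differed by 1.37-fold. The percentile of this list was 88.5 among unmatched lists and 83.9 among length-matched lists, so it then no longer stood apart.

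Of 26 expressed matrix proteases and inhibitors, 12 were higher in the SKP library, 3 were lower and 11 were neither, with a median of 0.87 above all random lists. Mmp9, the gelatinase of tissue remodelling, stood at 261 RPKM against 1.96 (133-fold, 111 to 161). Mmp3, which encodes stromelysin, was among the most abundant SKP transcripts at 1860.4 RPKM against 27.1 (68.7-fold, 64.4 to 73.4). The urokinase gene Plau was 28.6-fold higher (26.4 to 31.0), the macrophage elastase gene Mmp12 31.1-fold and the gelatinase gene Mmp2 4.30-fold. The 3 lower members were Adamts5, Timp3 and Mmp23. Of 16 expressed integrins, 7 were higher, 2 were lower and 7 were neither, with a median of 0.75 at percentile 99.98. Itga2, a collagen receptor subunit, was 105-fold higher in the SKP library (52.9 to 243), the laminin receptor subunit gene Itga6 16.4-fold and the leukocyte integrin gene Itgb2 19.2-fold. Itga11, the collagen receptor subunit of myofibroblasts, was 14.1-fold higher in fibroblasts (12.9 to 15.4), and Itga3 was also lower in the SKP library. Leukocyte and mast cell markers were higher in the same library, with list medians of 2.70 and 6.78 on the log2 scale.

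Markers used to define SKPs and the neural crest did not stand apart as a group: of 17 expressed members 5 were higher in the SKP library, 4 were lower and 8 were neither, with a median of -0.14 at percentile 18.1. Nes, the neural progenitor filament nestin, stood at 28.2 RPKM against 6.30 (4.48-fold, 4.13 to 4.87), and the homeobox gene Msx1 had 89 reads against 0, at least 28.8-fold higher against a floor of 3 reads, with an exact interval limit of 23.0. Tfap2a (2.80-fold), Id2 (2.73-fold) and Sox2, a stem cell transcription factor (1.83 RPKM against 0.818, 2.23-fold, 1.5001 to 3.38), were the other members higher in the SKP library. Lower there were Dlx2 (38.1-fold, 12.7 to 188), Sox10, the regulator of glial and pigment lineages (4.24-fold, 3.09 to 5.92), Foxd3 (3.75-fold) and the endothelin receptor gene Ednrb (2.42-fold). The mesenchymal regulators Snai1 (117 RPKM against 81.5), Twist1 (55.0 against 60.6), Twist2 (122 against 155) and Snai2 (29.0 against 53.9), and also Sox9 (9.05 against 6.77), Zic1 (20.4 against 16.3), Ets1 (11.2 against 15.1) and the neurotrophin receptor gene Ngfr (4.63 against 7.33), were under 2-fold apart. Sox5, Msx2, Dlx1, Pax3 and Tfap2b lay below the expression filter in both libraries, with 72, 9, 2, 1 and 2 SKP reads against 8, 18, 6, 9 and 18. Without the expression filter the list's median was -0.39 at percentile 0.71, below the limit. On the log2(RPKM + 1) scale 3 members were higher and 3 lower, and Sox2 (0.64) and Foxd3 (-0.73) were no longer 2-fold apart, and with genes at RPKM 5 or more 2 were higher and 1 was lower.

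Dermal papilla markers, which label the signalling cells at the base of the hair follicle, had 11 of 21 expressed members higher in the SKP library, 2 lower and 8 neither. Their median of 1.24 lay above all random lists. Spon1 was 89.4-fold higher (74.3 to 109), the lysophospholipase gene Enpp2 78.0-fold (51.8 to 123), the protease gene Corin 64.8-fold (25.03 to 239.7), Bmp6 21.1-fold, Serpine2 4.65-fold and Crabp1 3.39-fold. The 2 lower members were Fgf7 and the BMP antagonist gene Nog. The median was 0.75, with 8 of 21 higher, on the log2(RPKM + 1) scale and 0.71, with 4 of 12 higher, at RPKM 5 or more. Of 12 pluripotency genes with reads only 6 were expressed, 1 higher (Klf2, 2.08-fold), 1 lower (Myc, 2.66-fold higher in fibroblasts) and 4 neither, at percentile 86.9 with a median of 0.32, which was 0.53 without the filter and -0.15 at RPKM 5 or more. Among these, Tbx3 stood at 2.56 RPKM against 1.62 and Klf4 at 26.1 against 42.1. Schwann cell and glial markers had 4 of 15 expressed members higher, 7 lower and 4 neither, with a median of -0.34 at percentile 4.45. The growth cone protein gene Gap43 was 3.89-fold higher and the sodium channel gene Scn7a 14.6-fold, while the myelin gene Mbp (4.26-fold) and L1cam (3.98-fold) were higher in fibroblasts and the myelin gene Pmp22 differed by 1.26-fold. On the log2(RPKM + 1) scale only 2 glial members were higher and 1 was lower, and of the 3 at RPKM 5 or more 1 was higher and 0 were lower, with a median of 0.07. Among random lists that were unmatched the glial percentile was 2.35, past the limit. Of 6 expressed neuronal markers 2 were higher, 2 were lower and 2 were neither, with a median of -0.87 at percentile 0.36. The neurofilament gene Nefl had 147 reads against 1 and Mtap2 was 13.7-fold higher, whereas Tubb3 was 8.61-fold and Uchl1 3.64-fold higher in fibroblasts and the adhesion molecule gene Ncam1 differed by 1.73-fold. Without the filter the neuronal median was 0.04 at percentile 36.1, and with genes at RPKM 5 or more it was -0.79 at percentile 5.8, so that call was not kept.

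Markers of several other skin cell types were higher in the SKP library. Of 8 expressed mast cell markers 7 were higher and 1, Gata2, was lower, with a median of 6.78 above all random lists. The mast cell chymase gene Cma1 had 285 reads against 1, the histamine-forming enzyme gene Hdc 119 against 1, and the growth factor receptor gene Kit 117 against 1. Only 1 of these markers reached RPKM 1 in the fibroblast library. All 13 expressed keratinocyte markers were higher in the SKP library, with a median of 3.37 at percentile 99.99. The basal keratin genes Krt14 (13.4 RPKM against 0.970) and Krt5 (9.13 against 0.843) were 13.8-fold and 10.8-fold higher, and Ivl, a cornified envelope protein gene, had 130 reads against 0, at least 42.1-fold against the floor (exact limit 33.7). Krt6a was 27.2-fold higher, with reads that may be shared with its copy, Lor had 36 reads against 1 and Krtdap 47 against 3. Of 7 expressed macrophage and leukocyte markers 6 were higher and 1, Cd14, was neither, with a median of 2.70 at percentile 99.9, among them Lyz2 (12.7 RPKM against 1.95), Cd68 (8.90 against 1.62), Fcer1g (7.77-fold) and Ctss and Fcgr3, with 3 and 1 fibroblast reads. Only 2 keratinocyte and 2 leukocyte markers reached RPKM 1 in the fibroblast library. For members that passed the expression filter through the SKP library alone, the filter itself favoured that direction. Without the filter 14 of 20 leukocyte markers were higher and 0 were lower, with a median of 2.31. Adipocyte markers had 11 of 13 expressed members higher, 1 lower and 1, Pparg, neither, with a median of 3.44 above all random lists. Adipoq, the hormone adiponectin, was 202-fold higher (78.4 to 741), the fatty acid transporter gene Cd36 113-fold (70.4 to 194) and the desaturase gene Scd1 3.38-fold, and the lipid droplet gene Plin1 had 425 reads against 3. Lpl, which releases fatty acids from lipoproteins, was 2.15-fold higher in fibroblasts. These medians depend on the few fibroblast reads: on the log2(RPKM + 1) scale they were 2.66 for mast cell markers, with 7 higher and 0 lower, so that Gata2 was no longer called, 1.46 for keratinocyte markers, with 10 of 13 higher, 1.55 for macrophage and leukocyte markers, with 6 of 7 higher, and 1.75 for adipocyte markers, with 11 of 13 higher.

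Muscle, vascular and skeletal markers were examined in the same way. Of 16 expressed skeletal muscle markers 10 were higher in the SKP library, 0 were lower and 6 were neither, with a median of 1.25 above all random lists. The perinatal myosin gene Myh8 was 9.27-fold higher, creatine kinase Ckm 5.93-fold, the acetylcholine receptor gene Chrna1 3.91-fold and the myogenic regulator Myod1 3.21-fold, while Mylpf and Acta1 differed by 1.94-fold and 1.28-fold. Of 8 expressed pericyte markers 4 were higher, 2 were lower and 2 were neither, with a median of 1.12 at percentile 99.9. Anpep was 6.86-fold higher, Ndufa4l2 5.71-fold and Rgs5 7.19-fold, while Rgs4 was 13.1-fold higher in fibroblasts with Mcam and Pdgfrb differed by 1.19-fold. Of 7 expressed bone and cartilage markers 4 were higher, 1 (Omd) was lower and 2 were neither, with a median of 1.24 at percentile 99.7, among them Spp1 (4.50-fold, 4.44 to 4.57) and the osteoblast regulator Sp7 (2.95-fold). The bone and cartilage median was 0.75 on the log2(RPKM + 1) scale, with 3 of 7 higher, and the pericyte median was 0.63 without the filter. Endothelial markers, with 5 expressed, had 2 higher, Plvap (15.3-fold) and Cdh5 (4.54-fold), 0 lower and 3 neither (Flt1, Egfl7 and Eng), at percentile 83.4 with a median of 0.38, or 0.75 without the filter. Of 9 melanocyte markers with reads only 2 were expressed, Kit and Mitf (5.35-fold higher in the SKP library), so that list was not ranked.

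**Figure D2:**
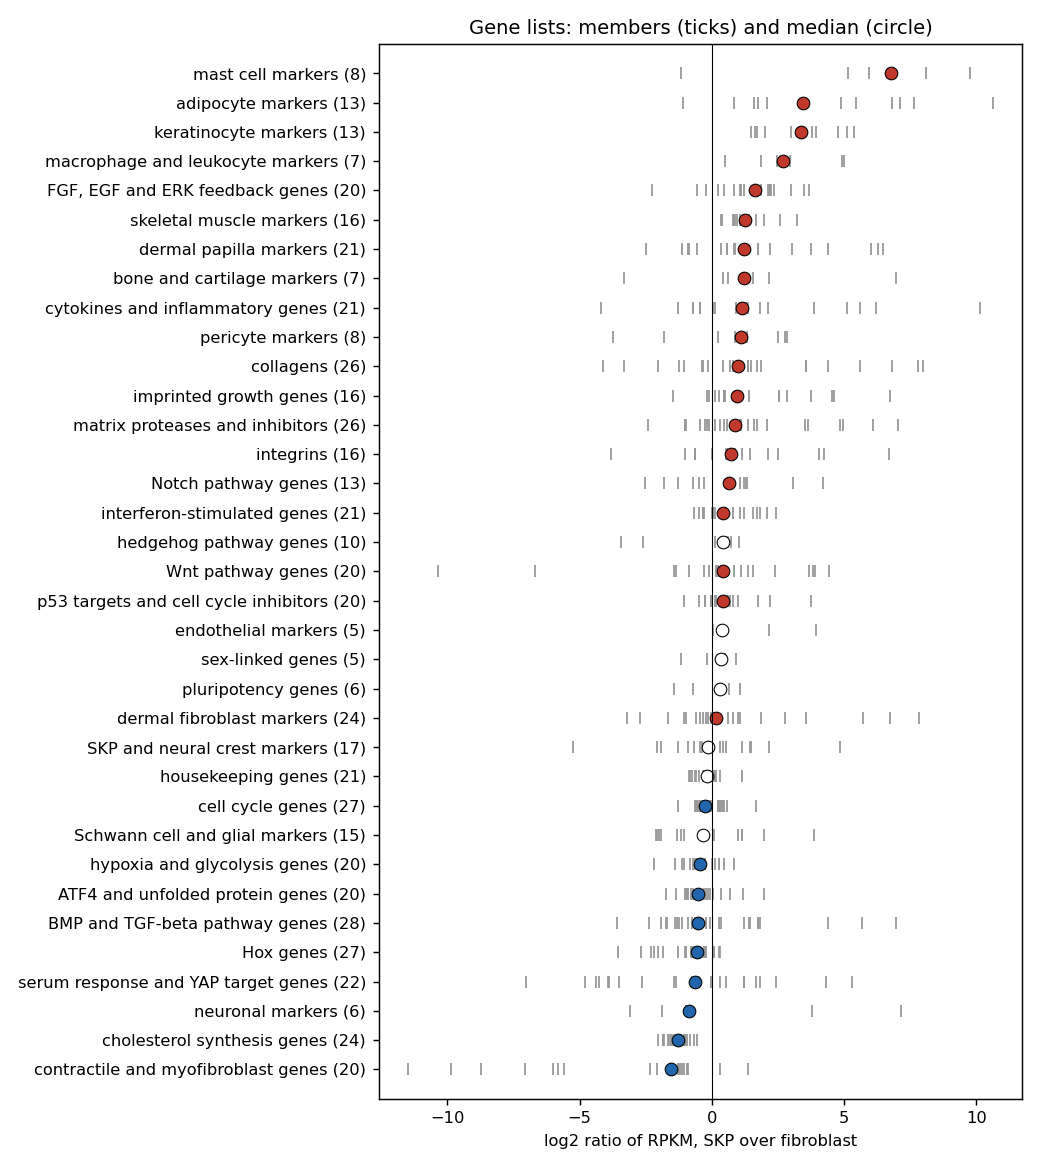
Log2 ratio of RPKM, SKP over fibroblast (x axis), of the expressed members of each ranked list (ticks, their number in parentheses) and of the list median (circle). Red circles are the 19 lists above and blue circles the 9 lists below the matched random lists, white circles the 7 lists within them, from the mast cell markers at 6.78 to the contractile genes at -1.53.

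The list of feedback genes of FGF, EGF and ERK signalling, which also holds receptor genes such as Fgfr1 and Fgfr2, was higher in the SKP library for 14 of 20 expressed members. It had 1 lower, 5 neither and a median of 1.62 above all random lists. The ERK target transcription factor gene Etv1 was 12.7-fold higher (11.1 to 14.6), the ERK phosphatase genes Dusp6 11.2-fold (10.1 to 12.3) and Dusp5 5.12-fold, the receptor signalling inhibitor gene Spry4 7.95-fold (7.39 to 8.56) and Lrig1 3.60-fold. Fgfr1 stood at 152 RPKM against 84.5, and the 1 lower member was Fgfr2. FGF2 and EGF were in the SKP medium and are not named for the fibroblast medium.

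Wnt pathway genes divided, with 8 of 20 expressed members higher in the SKP library, 4 lower and 8 neither, and a median of 0.42 at percentile 98.4. Wnt2 was 21.7-fold higher (11.6 to 45.8), the secreted inhibitor gene Sfrp2 2.59-fold and Sfrp5, at 46 reads against 0, at least 14.9-fold against the floor (exact limit 11.6), whereas Lgr5, Wnt4, Nkd1 and Nkd2 were lower. Without the filter the Wnt median was 0.85, with 13 of 31 higher and 5 lower. Of 13 expressed Notch genes 6 were higher, 3 were lower and 4 were neither, with a median of 0.66 at percentile 98.8. Notch4 was 18.7-fold higher, Dtx4 8.31-fold and Notch2 2.08-fold, while the ligand genes Jag1 (3.53-fold) and Dner (5.68-fold) and also Lfng were higher in fibroblasts, and the target gene Hes1 stood at 26.1 RPKM against 43.0. The Notch percentile was 94.2 with genes at RPKM 5 or more (median 0.37) and 93.5 on the log2(RPKM + 1) scale (median 0.32), so the list then no longer stood apart. Hedgehog genes had 1 of 10 expressed members higher, the co-receptor gene Boc (2.04-fold), 2 lower, among them Foxf1 (10.7-fold), and 7 neither, with a median of 0.43 at percentile 93.4. Ptch1 (1.18 RPKM against 0.707), Smo (35.5 against 32.9) and Gas1 (148 against 106) were among the last, and with genes at RPKM 5 or more the percentile was 98.3, past the limit.

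BMP and TGF-beta pathway genes had 9 of 28 expressed members higher in the SKP library, 9 lower and 10 neither, and their median of -0.50 lay below all random lists. The BMP ligand genes Bmp2 (21.7 RPKM against 0.171, 127-fold, 64.0 to 294), Bmp7 (50.8-fold, with 3 fibroblast reads) and Bmp6 were higher. The BMP antagonist gene Grem1 (5.15-fold, 4.91 to 5.41) and the BMP response gene Id4 (11.97-fold, 9.72 to 14.9) were higher in fibroblasts, and the protease gene Bmp1 differed by 1.55-fold. Hox genes, which hold positional identity, had 0 of 27 expressed members higher, 8 lower and 19 neither, with a median of -0.57 below all random lists. Hoxb9 was 11.6-fold higher in fibroblasts (9.92 to 13.5), Hoxc13 6.33-fold, Hoxa11 4.95-fold and Hoxc8 2.39-fold, while the most abundant member, Hoxc6, stood at 47.5 RPKM against 68.1.

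Imprinted growth genes were higher in the SKP library for 8 of 16 expressed members, with 1 lower, 7 neither and a median of 0.95 above all random lists. Dlk1, a Notch-like regulator of preadipocytes, stood at 196 RPKM against 1.85 (106-fold, 90.9 to 125), H19 was 24.7-fold higher (24.0 to 25.4), its neighbour Igf2, a fetal growth factor, 23.3-fold (22.0 to 24.6) and the cyclin kinase inhibitor gene Cdkn1c 13.5-fold (12.2 to 14.9). The 1 lower member was Meg3, at 31.3 RPKM against 86.1. With genes at RPKM 5 or more the median was 1.97, with 8 of 14 higher. Of 20 expressed p53 targets and cell cycle inhibitors 3 were higher, Cdkn1c, Cdkn2a (4.66-fold) and Cdkn2b (3.37-fold), 1 was lower, Pmaip1 (2.05-fold), and 16 were neither, with a median of 0.41 at percentile 99.9. Cdkn1a (292 RPKM against 301) and Ccng1 (226 against 159) were among the last. The 3 higher members are cyclin kinase inhibitor genes, and the percentile was not computed for p53 targets alone. Cell cycle genes were close in both libraries, with 1 of 27 higher, the G1 cyclin gene Ccnd1 (3.15-fold, 3.06 to 3.25), 1 lower, the ribonucleotide reductase gene Rrm2 (2.45-fold, 2.23 to 2.70), and 25 neither. Their median of -0.24 lay at percentile 1.89, and examples were Pcna (79.9 RPKM against 64.5), Tk1 (12.2 against 18.1) and Birc5 (4.85 against 7.54). That percentile was 2.5 among unmatched lists and 7.75 on the log2(RPKM + 1) scale, no longer past the limit.

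**Figure D3:**
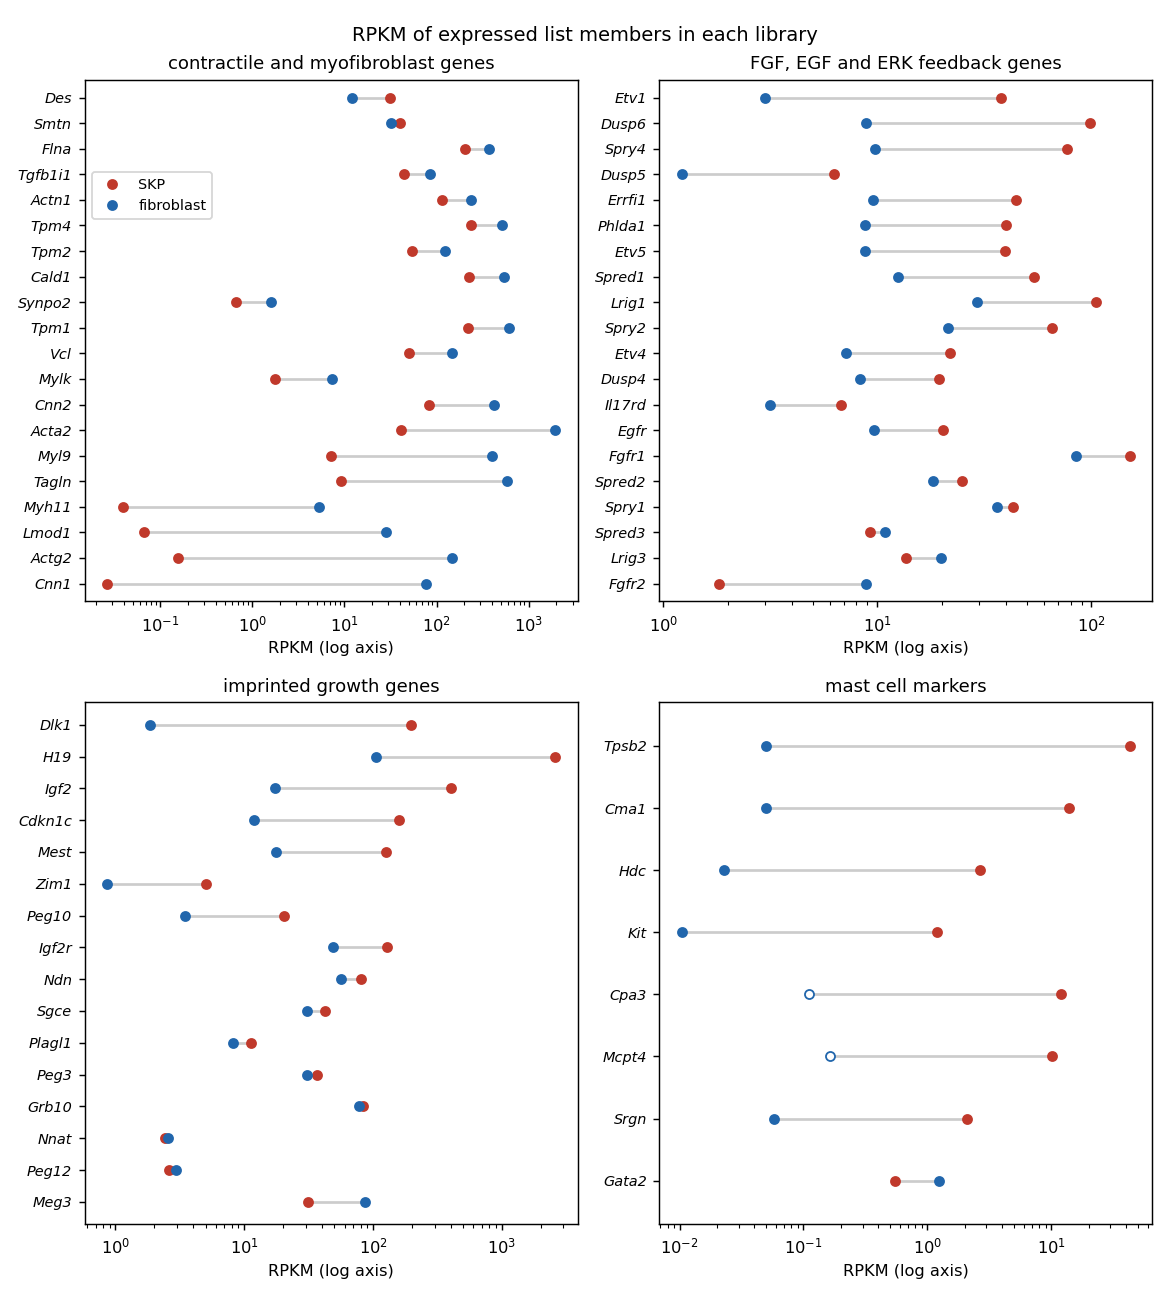
RPKM (x axis, log scale) of the expressed members of 4 lists in the SKP library (red) and the fibroblast library (blue), with grey lines joining the libraries and open circles for 0 reads drawn at the level of 3 reads. Most contractile genes lie to the right in fibroblasts (Acta2 at 1953 against 41.0), whereas most feedback, imprinted and mast cell genes lie to the right in SKPs (H19 at 2599.6 against 105).

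All 24 cholesterol synthesis genes were lower in the SKP library by value, 19 of them by at least 2-fold, with a median of -1.28 below all random lists. Fdps, which makes farnesyl diphosphate, was 4.13-fold higher in fibroblasts (3.91 to 4.37), the lanosterol synthase gene Lss 3.63-fold, the isomerase gene Idi1 3.58-fold, Pmvk 3.51-fold and Hmgcs1, at the entry to the pathway, 3.05-fold. The 5 members that were neither were Srebf2, Dhcr7, Stard4, Mvk and Insig1. Hypoxia and glycolysis genes had 0 of 20 expressed members higher, 4 lower and 16 neither, with a median of -0.42 at percentile 0.26. The lower members were the vasodilator gene Adm (4.54-fold, 3.85 to 5.38), Aldoc (2.62-fold), the angiogenic factor gene Vegfa (2.16-fold) and Eno1 (2.08-fold), whose low coverage of its length (28.1% and 29.7%) leaves its counts uncertain. The glycolytic genes Aldoa and Ldha differed by 1.36-fold and 1.62-fold in the same direction. ATF4 and unfolded protein genes had 2 of 20 higher, 3 lower and 15 neither, with a median of -0.50 at percentile 0.05. The cystine transporter gene Slc7a11 (3.90-fold) and Vldlr (2.24-fold) were higher, and Chac1 (3.33-fold), Trib3 (2.53-fold) and Ddit3 were lower, while Atf4 stood at 199 RPKM against 276 and the chaperone gene Hspa5 at 359 against 282.

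Cytokines and inflammatory genes had 12 of 21 expressed members higher in the SKP library, 2 lower and 7 neither, with a median of 1.15 above all random lists. Besides Lcn2, the acute phase gene Saa3 (228 RPKM against 3.07) was 74.4-fold higher (52.0 to 111), complement C3 49.3-fold (37.9 to 65.5), the alarmin gene Il33 34.5-fold, the eosinophil chemokine gene Ccl11 14.6-fold and the monocyte chemokine gene Ccl2 2.61-fold. The 2 lower members were Cxcl14 and Il6, the latter with 2 reads against 35. Interferon-stimulated genes had 7 of 21 higher, 0 lower and 14 neither, with a median of 0.44 at percentile 99.96, among them Oasl1 (5.43-fold), Cxcl10 (4.30-fold), Rsad2 (3.57-fold) and Ifi27l2a (3.29-fold). Isg15 (86.7 RPKM against 140) and Bst2 (111 against 138) were under 2-fold apart in the other direction. Leukocyte and mast cell markers, with medians of 2.70 and 6.78, were higher in the same library as both groups.

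Housekeeping genes had 1 of 21 members at least 2-fold apart, B2m (2.19-fold higher in the SKP library), 20 neither and a median of -0.17 at percentile 30.9. Gapdh differed by 1.68-fold at a coverage of its length of only 20.9% and 25.3%, Tfrc by 1.82-fold, Actb by 1.76-fold and Eef1a1 by 1.26-fold, all higher in fibroblasts. Both libraries held reads of Xist and of the Y-linked genes. The sex-linked list pools them, so its median has no single direction and nothing is read from it. Xist stood at 19.7 RPKM against 10.4, Uty at 4.11 against 2.92, Kdm5d at 3.48 against 2.76 and Ddx3y at 5.68 against 6.36, while Eif2s3y was 2.21-fold higher in fibroblasts, so that 1 of 5 sex-linked genes was lower in the SKP library and 4 were neither, at percentile 83.9 with a median of 0.33, or -0.16 for the 3 at RPKM 5 or more.

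The authors' deposited table of filtered genes held 2659 genes, 1823 higher in the SKP library and 836 higher in the fibroblast library. In the authors' deposited table these were exactly the genes with an absolute log2 ratio of at least 1 and an FDR of at most 0.001, from a test on the reads of 2 libraries, which compares those libraries and not the cell types. Of the 2227 genes called here, 2163 were in the authors' deposited table with 0 in the opposite direction, and 64 were not. Both sets of calls start from the same read counts of these 2 libraries and use a 2-fold limit. The shared calls and directions therefore follow from the shared data and are no independent check. The 496 genes of the authors' deposited table that were not called here all lay below the expression filter.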

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

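Lists matched on gene length were the only alternative chosen after the results were seen. The 3 scalings shift every gene alike and so leave list percentiles as they were. Under the other 5 alternatives 156 of 173 list values kept the call, and 27 of 35 lists kept it under all of them. With 1 library per group no library could be left out. No paired analysis was possible because each group had 1 library. Counts followed the filters by construction: genes at least 2-fold higher in SKP numbered 2197 without the expression filter, 828 at RPKM 5 or more and 705 at 4-fold, and genes at least 2-fold higher in fibroblast 478 at RPKM 5 or more, 241 at 4-fold, 508 on the log2(RPKM + 1) scale and 510.0 where the interval had to exclude 2-fold. The share of calls higher in the SKP library was 65.3%, and 74.5% at 4-fold. Ratios of genes with few reads in a library rest on wide intervals.

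For the lists whose call changed, the cause was not tested. Without the expression filter the percentile was 0.71 for SKP and neural crest markers, 96.5 for dermal fibroblast markers and 36.1 for neuronal markers. At RPKM 5 or more it was 7 for serum response and YAP targets, 5.8 for neuronal markers, 2.58 for cell cycle genes, 94.2 for Notch genes and 98.3 for hedgehog genes. On the log2(RPKM + 1) scale it was 1.4 for Schwann cell markers, 7.75 for cell cycle genes and 93.5 for Notch genes. Among unmatched lists it was 88.5 for dermal fibroblast markers, 2.35 for Schwann cell markers and 2.5 for cell cycle genes. Among length-matched lists it was 83.9, 2.35 and 2.67 for the same lists.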

Other observations

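All tests of explanations below were chosen only after the results were seen. Beyond the fixed lists, 723 gene ontology terms with 15 to 150 expressed genes were ranked in the same way, with matching on expression and on length. Under both matchings 105 terms lay above and 23 below their random lists, where about 36.15 would lie outside by chance for a single matching if genes were independent, which they are not. The terms and genes named here were chosen after their values were seen. Genes of the ribosome had slightly lower medians in the SKP library: the 35 expressed genes of the small subunit had a median of -0.49 and the 40 of the large subunit a median of -0.46 on the log2 scale, with 0 genes 2-fold apart and single ratios of the small subunit from 0.04 for Rps4y2 to -0.91 for Rps12. Their expression-matched random lists had medians of -0.16 and -0.14, so part of the shift was shared by genes of like abundance. Some members had low coverage of their length in the SKP and fibroblast libraries, such as Rpl26 (21.1% and 20.6%) and Rpl37 (26.2% and 29.3%). Their counts are therefore uncertain. Rps2 stood at 883 RPKM against 1539 and Rplp1 at 1309.6 against 2256. Of 44 genes of the tRNA aminoacylation term, with a median of -0.38, only Ptges3l was at least 2-fold lower, with 40 SKP reads against 89. Examples under 2-fold were the glycine enzyme gene Gars (101 RPKM against 174) and the isoleucine enzyme gene Iars (28.9 against 52.99).

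Inflammatory terms lay on the other side. Of 21 expressed genes of cytokine activity 14 were higher in the SKP library and 1 was lower, with a median of 1.39, and leukocyte chemotaxis had 10 of 19 higher and 2 lower (median 1.28). Fcer1g, Fcgr3 and Itgb2 of that term are themselves leukocyte genes, and leukocyte and mast cell markers were higher in the same library, with list medians of 2.70 and 6.78. The monocyte chemokine gene Ccl12 stood at 83.3 RPKM against 1.11, and the adhesion molecule gene Icam1 at 99.1 against 12.2 in the response to lipopolysaccharide, where 20 of 39 genes were higher and 2 were lower (median 1.17). Fat cell differentiation had 14 of 27 genes higher and 2 lower (median 1.12), with the adipokine gene Rarres2 at 142 RPKM against 7.29.

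Markers of mast cells, adipocytes, keratinocytes and leukocytes were higher in the SKP library. All 13 expressed keratinocyte markers were higher, up to 13.4 RPKM for Krt14, and so were all 20 counted without the expression filter. Being higher is the pattern itself, and the 2 markers that reached RPKM 1 in fibroblasts (100% higher) are too few to decide, so a small share of keratinocytes among the SKP spheres cannot be told apart from keratinocyte genes expressed by the SKPs. Of the 6 adipocyte markers at RPKM 1 or more in fibroblasts 4 (66.7%) were higher, with Fabp4 at 243 RPKM against 22.6 and Lpl lower, so a small share of adipocytes cannot be told apart from fat genes expressed by the SKPs. A share of mast cells or leukocytes, the purity of the cultures, their age and their medium were not tested.

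Contractile genes were lower in the SKP library. A few abundant genes taking a different share of the reads would shift all genes alike, which was argued against, since the list median lay -1.53 from the median of all other expressed genes (bootstrap interval -5.70 to -1.15). That distance repeats the list's own low median and is no independent check. The argument is only that a shift of all genes alike cannot set a list apart from the rest. With 1 library per group the bootstrap could only resample genes, which are not independent. A trend of the ratio with gene length was argued against as the whole cause, with the list at percentile 0 among length-matched lists, although ratios did follow length (rho 0.172 across expressed genes, which are not independent). What stays open is culture medium and attachment in place of cell type: the number of media in which both cell types were grown was 0, so serum and attachment cannot be told apart from cell type here. A cell type difference is a hypothesis that these libraries leave untested.

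Cholesterol synthesis genes were lower in the SKP library. A few abundant genes taking a different share of the reads was argued against here too, with the list median -1.28 from that of all other expressed genes (bootstrap interval -1.48 to -1.17). This distance, too, repeats the list's own low median, and its interval treats genes as independent. A trend of the ratio with gene length was argued against as the whole cause, with the list at percentile 0 among length-matched lists. As for the contractile genes, culture medium and attachment in place of cell type stays open, with 0 media shared by the cell types, and cannot be told apart from cell type. Sterol supply and growth rate were not tested.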
